A study of Sus scrofa with 75 samples.

How the data were processed

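The deposited table held read counts per gene symbol for 75 libraries of total RNA extracted with an RNeasy kit, per the labels' protocols. The counts were whole numbers that the authors deposited without normalization, and the submitters' processing notes name DESeq2, with no version, and the pig genome build Sscrofa11.1. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here, so overlapping genes, close paralogs (such as the SLA genes) and antisense genes cannot be separated. The table had 15668 gene rows with counts, and 1 row of pathway text without counts was left out. Of the symbols, 15004 were matched to RefSeq symbols of Sscrofa11.1, which gave the coordinates, and 14132 to the gene name table. Every column was mapped to its library by the library name in the labels. In every library even low counts were more frequent than odd ones, 1.19 to 1.54 times over counts of 1 to 40, so that 1 count is not always 1 independent read pair. Intervals from counting statistics would be too narrow, and the errors given come from the spread between libraries. No 2 libraries of 1 group had identical counts, and pairs within groups differed by far more than sampling noise (chi-square per degree of freedom of 37.5 or more).

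Each tissue was fitted apart. Genes were kept with filterByExpr on the 4 groups, which left 13609 genes in small intestine, 12545 in liver and 12355 in muscle. Counts were scaled by TMM and fitted with 1 mean per group by the quasi-likelihood method of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. Contrasts were birth weight (LBW minus NBW, averaged over replacer labels), replacer (HFHP minus unnamed, averaged over birth weight classes) and their interaction. Tests were two-sided with Benjamini-Hochberg adjusted p under 0.05 and no fold minimum. The SE of a fold change is the fold change over the square root of its F statistic. Levels are CPM, counts scaled to library totals of 1e+06, and log2 CPM used a prior count of 2. Across TMM, RLE and no scaling the median fold change of all genes stayed within 0.1 of 0 on the log2 scale, except 0.15 for the muscle interaction without scaling. The 57 gene lists covered functions, cell types of each tissue, other cell types and RNA quality. They were fixed before the data were examined and tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the lists of 1 tissue and contrast with at least 5 tested members. No list call of any tissue held at 0.05 with an estimated correlation, so the report gives that p beside each call. Of 984 listed genes 860 were among the rows. The counts over a list alone adjusted the edgeR p-values of its members only.

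Named genes followed a rule fixed before the data were examined. For each contrast, called genes with an average log2 CPM of at least 1 and the largest fold changes were to be named, and where a direction had none, the 3 with the smallest p. From each list, up to 4 members with the smallest p among those called over all genes or over the list alone could be named, or up to 2 from a list without a call. The text names a part of the genes that qualify. Alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter (genes with at least 1 count), a filter of at least 5 CPM in at least 5 libraries, the replicate number as a block, 1 surrogate variable (sva 3.50.0), robust estimation, leaving out mitochondrially encoded genes and leaving out each library in turn. For lists they were an estimated correlation, fry, the block and the surrogate variable. A covariate from Y-linked genes could not be made because none of the 9 listed genes was among the rows used. The scripts were tested on simulated counts with 200 changed genes in each contrast, drawn from the real means, library sizes and dispersions. For the replacer, a 2-fold change was recovered for 79.1% of changed genes in small intestine, 79.1% in liver and 74.6% in muscle, and a 1.5-fold change for 56.7%, 52.2% and 38.8%. For birth weight, a 2-fold change was recovered for 80.6%, 77.6% and 74.6%, and for the interaction for 44.8%, 38.8% and 20.9%. These ran on 12234 to 13531 genes drawn independently of each other, which real genes are not. In simulated lists shifted by 0.4 on the log2 scale camera called 20 of 20 in each tissue, and of 20 unshifted lists it called 1 in muscle and 0 elsewhere. These lists held random genes, also drawn independently, so they do not show how often camera calls unshifted lists of correlated genes.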

Results

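Gene expression was measured by RNA sequencing in small intestine, liver and semitendinosus muscle, a muscle of the hind limb, of piglets reared on milk replacer. The 75 libraries fall into 12 groups, defined by 3 tissues, by birth weight class and by the replacer named in the sample title. Low birth weight (LBW) piglets weighed less than 1000 g at birth and normal birth weight (NBW) piglets 1000 g or more. The study fed 2 replacers with the same fat content (32% of dry matter): HFHP, with 22.2% crude protein before mixing and 4.4% in the prepared milk, and HFLP, with 18.0% and 3.6%. Titles named HFHP or no replacer. The libraries without a replacer in the title are called unnamed here, because the labels do not state that they received HFLP. The small intestine groups held 8 NBW HFHP, 8 NBW unnamed, 6 LBW HFHP and 7 LBW unnamed libraries. The liver groups held 6, 5, 5 and 6 libraries in the same order, and the muscle groups 6, 6, 5 and 7. Library totals were 28.7 to 33.9 M counts in small intestine, 30.7 to 34.9 M in liver and 25.5 to 30.8 M in muscle (M, 1e+06). The labels give no age, sex, litter, experiment, round, rearing deck or intestinal segment. They do not say that each library came from a separate piglet, so the edgeR p-values measure the spread between these libraries. The limma camera p-values compare the genes of a list with the other genes tested. They depend on the preset inter-gene correlation and do not measure the spread between libraries alone. The study describes 2 experiments, with 40 piglets (20 LBW and 20 NBW) on 4 rescue decks in each round. Piglets left the sow by 12 hours after birth. No deck, round or experiment term could be fitted, so such effects were not separated from birth weight class or replacer. The factorial design asked how birth weight class, replacer protein and their combination were reflected in each tissue. Fold changes are HFHP relative to unnamed or LBW relative to NBW, each averaged over the other factor, as log2 fold change ± SE, and group levels are mean ± SD.

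Members of the amino acid handling lists went both ways with HFHP in the small intestine. Of 16 peptide and amino acid transporters tested, 7 were lower and 4 higher with HFHP when adjusted over the list alone, and none passed over all genes tested. Among the lower members were SLC16A10, an aromatic amino acid transporter (-1.45 ± 0.42, adjusted p over the list alone = 0.00780 by the edgeR quasi-likelihood test), and SLC1A1, a glutamate and aspartate transporter (-0.93 ± 0.28). Among the higher members were SLC7A5, a transporter of large neutral amino acids (0.75 ± 0.20), and the glutamine transporter SLC1A5 (0.61 ± 0.18). Targets of ATF4, the transcription factor of the amino acid response, were higher as a list (median log2 fold change 0.34; limma camera adjusted p = 2.05e-05, adjusted p = 0.497 with an estimated correlation). Of its 30 members, 10 were higher and 1 lower over the list alone, including the cystine transporter SLC7A11 (log2 fold change 1.42, adjusted p over the list alone = 0.0130; chromosome 8, 88608083 to 88690589 of Sscrofa11.1) and the glycyl- and seryl-tRNA synthetases GARS1 (0.49 ± 0.13) and SARS1 (0.38 ± 0.11). SLC7A5 belongs to both lists. For the ATF4 counts, leaving out any 1 of 5 of the 29 libraries moved the higher count by over 1.5 times, between 4 (without NBW HFHP replicate 2) and 14 (without LBW unnamed replicate 3), and the lower member was lost or joined by others on leaving out 23. The transporter list as a whole was lower (median -0.29; limma camera adjusted p = 0.0359, adjusted p = 0.497 with an estimated correlation).

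The cell cycle list tested higher with HFHP in the small intestine, with all 35 fold changes above 0 (median 0.41; limma camera adjusted p = 1.00e-12, adjusted p = 0.497 with an estimated correlation). Over the list alone 13 members passed, among them KIF2C, a mitotic kinesin (0.58 ± 0.17), HMMR (0.54 ± 0.16) and the cyclin CCNB1 (0.63 ± 0.21). For this count, leaving out any 1 of 21 of the 29 libraries moved it by over 1.5 times, between 0 (without NBW HFHP replicate 2) and 31 (without LBW unnamed replicate 3). The list averaged 5.97 ± 0.30 log2 CPM in LBW HFHP and 5.24 ± 0.48 in LBW unnamed libraries, against 5.87 ± 0.55 in NBW HFHP and 5.78 ± 0.41 in NBW unnamed libraries. Genes of the endocytic enterocytes of the neonatal gut, which take up and digest milk protein inside the cell, were lower (median -0.45; limma camera adjusted p = 5.97e-04, adjusted p = 0.497 with an estimated correlation). The 3 of 11 members lower over the list alone were the sialidase NEU1 (-1.10 ± 0.27) and the lysosomal proteases CTSB (-0.32 ± 0.10) and LGMN (-0.52 ± 0.17), a count that 6 of the 29 libraries moved by over 1.5 times, up to 7 without NBW HFHP replicate 3. The endocytic mean went from 6.91 ± 0.41 log2 CPM unnamed to 6.73 ± 0.43 with HFHP in NBW, and from 7.41 ± 0.53 to 6.57 ± 0.45 in LBW libraries. Of 14 brush border hydrolases, NAALADL1 (-0.74 ± 0.21), MME (-0.70 ± 0.22) and MEP1B (-0.84 ± 0.27) were lower over the list alone, and TMPRSS15, the enteropeptidase that activates trypsinogen, was higher (2.43 ± 0.63), though not without LBW HFHP replicate 5. The count of lower hydrolases moved so with 3 libraries, up to 5 without NBW HFHP replicate 3. That list tested lower (median -0.17; limma camera adjusted p = 0.0151, adjusted p = 0.497 with an estimated correlation), while the mean of its fold changes was 0.06. Its median ran from -0.27 (without LBW HFHP replicate 5) to -0.11 (without LBW HFHP replicate 6) with 1 library left out. The interferon response list had all 29 fold changes above 0 (median 0.53; limma camera adjusted p = 1.55e-10, adjusted p = 0.497 with an estimated correlation), with no member past the threshold over the list alone, but 18 passed without LBW unnamed replicate 3.

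Markers of intestinal position moved in the same comparison. The distal small intestine list was lower with HFHP (median -0.54; limma camera adjusted p = 0.0112, adjusted p = 0.497 with an estimated correlation), with neurotensin, NTS, lower over the list alone (-0.86 ± 0.28). The median of the list ran from -0.61 (without LBW HFHP replicate 4) to -0.35 (without LBW unnamed replicate 7) with 1 library left out. Among proximal markers PDX1, a duodenal transcription factor, was higher (2.88 ± 0.68) and BTD lower (-0.31 ± 0.11) over the list alone, which as a whole did not pass (limma camera adjusted p = 0.861). The NTS call was lost on leaving out 1 of 17 of the 29 libraries (for example without NBW HFHP replicate 2), the BTD call on leaving out 1 of 13 (for example without NBW HFHP replicate 2) and the PDX1 call without LBW HFHP replicate 5. The distal list averaged 5.99 ± 1.32 log2 CPM in NBW HFHP and 6.06 ± 1.80 in LBW HFHP libraries. In NBW and LBW unnamed libraries it averaged 7.00 ± 0.58 and 6.87 ± 0.60. The ileal bile acid binding protein FABP6 ranged from -2.22 to 12.21 log2 CPM over the 29 libraries. Its lowest values lay mostly under HFHP: -2.22 in LBW HFHP replicate 5, and -1.27, -1.18 and 0.80 in NBW HFHP replicates 2, 5 and 6. LBW unnamed replicate 1 had 0.17. GATA4, a transcription factor of the upper small intestine, was -1.63 in LBW HFHP replicate 4 and -0.49 in LBW unnamed replicate 7. Glucocorticoid target genes went both ways: FKBP5 was higher (0.52 ± 0.12) and KLF15 (-0.85 ± 0.29) and DUSP1 (-0.38 ± 0.13) lower over the list alone. The lower count of 2 was 0 without NBW HFHP replicate 4 and the higher count of 1 was 4 without LBW HFHP replicate 4. These counts moved by over 1.5 times with 18 and 4 of the 29 libraries. As a list they did not pass (median 0.01, from -0.06 (without LBW unnamed replicate 3) to 0.12 (without LBW HFHP replicate 6), limma camera adjusted p = 0.949, lower by the test). Heat shock genes, a sign of RNA quality, had a median of 0.18 (limma camera adjusted p = 0.0377, adjusted p = 0.505 with an estimated correlation). Over the list alone 6 passed without LBW unnamed replicate 3. T and NK cell genes had a median of 0.33 (limma camera adjusted p = 8.64e-04, adjusted p = 0.505 with an estimated correlation). Genes of enteric neurons and glia had a median of -0.29 (limma camera adjusted p = 0.0235, adjusted p = 0.505 with an estimated correlation).

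Of 13609 genes tested one by one in the small intestine, none passed the edgeR quasi-likelihood test at an adjusted p of 0.05 for the replacer, while 2614 had an unadjusted p under 0.05. DESeq2 called 175 genes and limma voom with sample quality weights 1504. The smallest p-values among genes higher with HFHP, none of which passed, belonged to DCAF4 (0.60 ± 0.12), the Fanconi anaemia gene FANCA (0.61 ± 0.12) and the condensin II subunit NCAPD3 (0.44 ± 0.09). Among genes lower with HFHP they belonged to XK (-0.78 ± 0.16), TACC2 (-0.44 ± 0.09) and ZNF526 (-0.50 ± 0.11). Single libraries moved the count: without LBW unnamed replicate 3, edgeR called 1176 genes, and without NBW HFHP replicate 3 or LBW HFHP replicate 4 it called 21 and 15. Within LBW piglets alone, a comparison added after the data were seen, edgeR called NCAPD3, at 39.5 ± 6.48 CPM against 23.3 ± 3.26 CPM in unnamed libraries, and TACC2, at 64.2 ± 10.8 CPM against 108 ± 17.6 CPM, both with an adjusted p of 0.0392. Neither passed for the interaction (adjusted p = 0.472 for both), so the difference from NBW piglets was not established. Within NBW piglets, also added after the data were seen, edgeR, DESeq2 and limma voom called 0 genes. In edgeR 475 had an unadjusted p under 0.05, against 3177 within LBW. A share of 0.05 of the genes tested is 680. Random regroupings of the libraries had medians of 547 for the comparison within NBW and 564 for that within LBW. Differences between the 2 classes are what the interaction tests, and it called no gene. For the comparison within LBW, DESeq2 called 895 genes, limma voom 2556 and edgeR with the replicate block 1272. The count of 2 was 0 on leaving out any 1 of 17 libraries and 1784 without LBW unnamed replicate 3.

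In the small intestine, transcripts of cytotoxic lymphocytes were lower in LBW piglets without a named replacer and close to those of NBW piglets with HFHP. The T and NK cell mean was 4.50 ± 0.38 log2 CPM in LBW against 5.25 ± 0.28 in NBW unnamed libraries, and 5.13 ± 0.44 against 5.14 ± 0.44 with HFHP. Averaged over both replacers, all 21 T and NK cell genes had fold changes below 0 (median -0.36; limma camera adjusted p = 6.15e-13, adjusted p = 0.470 with an estimated correlation), and 8 passed over the list alone. They included the granule proteins NKG7 (-0.71 ± 0.16, adjusted p over the list alone = 0.00272 by edgeR; chromosome 6, 58496089 to 58497827 of Sscrofa11.1), GZMA (-0.87 ± 0.23), GNLY (-1.24 ± 0.33) and PRF1, perforin (-0.72 ± 0.21). The count stayed between 6 and 10 when single libraries were left out. MHC class II genes, called SLA in the pig, were also lower (median -0.33; limma camera adjusted p = 2.63e-07, adjusted p = 0.587 with an estimated correlation), with SLA-DRA (-0.43 ± 0.13), SLA-DMB (-0.43 ± 0.16) and SLA-DQB1 (-0.38 ± 0.15) lower over the list alone. The MHC class II mean was 6.62 ± 0.39 log2 CPM in LBW against 7.16 ± 0.35 in NBW unnamed libraries, and 7.05 ± 0.58 against 7.18 ± 0.28 with HFHP. The count of 3 moved by over 1.5 times on leaving out 20 of the 29 libraries, between 0 without NBW HFHP replicate 2 and 5 without LBW unnamed replicate 3. The interferon-inducible guanylate binding proteins, GBP1 (-1.30 ± 0.31) and GBP2 (adjusted p over the list alone = 0.0160), were lower over the interferon list alone, a count of 2 that was 5 without LBW unnamed replicate 3. That list did not pass, and its median of 0.04 and its test, which pointed lower, differed in sign (limma camera adjusted p = 0.0813). The sign of that median was not stable, as it ran from -0.11 (without LBW unnamed replicate 3) to 0.12 (without NBW HFHP replicate 6) with 1 library left out.

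Single members of other lists passed over their list alone in the birth weight comparison of the small intestine. Higher in LBW were GGT1, the brush border gamma-glutamyltransferase (0.87 ± 0.22), and TEK, an endothelial receptor (0.33 ± 0.09). Lower were NOS2, inducible nitric oxide synthase (-1.77 ± 0.50), the matrix protein POSTN (-0.71 ± 0.17) and the clock gene CIART (-0.56 ± 0.12). Of these, TEK was lost without NBW unnamed replicate 7 and NOS2 without NBW HFHP replicate 2, among others. The oxidative phosphorylation list was lower with no member past the threshold (median -0.16; limma camera adjusted p = 7.07e-13, adjusted p = 0.587 with an estimated correlation), and the cell cycle list likewise (median -0.26; limma camera adjusted p = 2.75e-08, adjusted p = 0.587 with an estimated correlation). By group means, the cell cycle list was lower in LBW piglets in unnamed libraries and not with HFHP. Its mean was 5.24 ± 0.48 log2 CPM in LBW against 5.78 ± 0.41 in NBW unnamed libraries, and 5.97 ± 0.30 against 5.87 ± 0.55 with HFHP. The interaction, given below, tests this difference and had no member past the threshold. The oxidative phosphorylation mean was 7.23 ± 0.22 log2 CPM in LBW against 7.29 ± 0.19 in NBW unnamed libraries, and 7.32 ± 0.23 against 7.52 ± 0.27 with HFHP. Signs of RNA quality moved too. Mitochondrially encoded genes had a median of -0.37 (limma camera adjusted p = 3.40e-05, adjusted p = 0.587 with an estimated correlation). Over the list alone 7 passed without NBW unnamed replicate 3. Immediate early genes had a median of -0.14 (limma camera adjusted p = 0.0247, adjusted p = 0.587 with an estimated correlation). Over the list alone 1 passed without LBW unnamed replicate 3. So did lists of other cells. Smooth muscle genes had a median of -0.20 (limma camera adjusted p = 0.00346, adjusted p = 0.587 with an estimated correlation). It ran from -0.32 to -0.11 with 1 library left out. Macrophage genes had a median of -0.13 (limma camera adjusted p = 6.48e-04, adjusted p = 0.587 with an estimated correlation). It ran from -0.24 to -0.07 with 1 library left out, and over the list alone 4 passed without LBW unnamed replicate 3. Plasma cell genes had a median of 0.58 (limma camera adjusted p = 0.00198, adjusted p = 0.655 with an estimated correlation). It ran from -0.21 to 1.52 with 1 library left out, and over the list alone 10 passed without NBW unnamed replicate 7. Endothelial genes had a median of 0.18 (limma camera adjusted p = 1.17e-04, adjusted p = 0.587 with an estimated correlation). It ran from 0.11 to 0.24 with 1 library left out. Of 11 hepatocyte markers 2 were lower over the list alone (median -1.05; limma camera adjusted p = 0.0870, adjusted p = 0.655 with an estimated correlation). With 1 library left out the median ran from -1.24 (without LBW HFHP replicate 5) to -0.20 (without NBW unnamed replicate 3). The count lay between 0 without NBW HFHP replicate 6 and 4 without LBW unnamed replicate 1. Transcripts of skeletal muscle, not expected of gut wall, were lower in LBW libraries for 6 of 8 members over the list alone, among them ACTA1 (-1.55 ± 0.59) and TNNT3 (-1.92 ± 0.66). For this count, leaving out any 1 of 15 of the 29 libraries moved it by over 1.5 times, between 0 (without NBW HFHP replicate 3) and 6 (without NBW HFHP replicate 2), and it was also 0 without NBW unnamed replicate 4, in which the list stood highest. Over all 13609 genes edgeR called none, with 805 at an unadjusted p under 0.05, against 16 calls by DESeq2 and 86 by limma voom. The smallest p-values of genes not passing were those of WWC2 (0.44 ± 0.11), the oestrogen sulfotransferase SULT1E1 (3.15 ± 0.78) and ATF6B (0.23 ± 0.06), with fold changes above 0. Those below 0 belonged to the chemokine receptor XCR1 (adjusted p = 0.108), CIART and GZMH (-0.87 ± 0.19). Without LBW unnamed replicate 3 edgeR called 30 genes, and without NBW HFHP replicate 6 it called 3.

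T and NK cell transcripts of the small intestine were lowest in LBW unnamed libraries. The T and NK cell list averaged 4.50 ± 0.38 log2 CPM in LBW unnamed libraries (n = 7), against 5.25 ± 0.28 in NBW unnamed (n = 8), 5.14 ± 0.44 in NBW HFHP (n = 8) and 5.13 ± 0.44 in LBW HFHP libraries (n = 6). For the interaction, the LBW minus NBW difference with HFHP less that without a named replacer, the list was higher (median 0.86; limma camera adjusted p = 6.76e-09, adjusted p = 0.802 with an estimated correlation). Of 21 members, 10 passed over the list alone, among them the T cell receptor and signalling genes CD8A (0.88 ± 0.26), ZAP70 (0.86 ± 0.30) and CD3D (0.88 ± 0.33). Leaving out any 1 of 12 of the 29 libraries moved this count by over 1.5 times, to 0 for example without NBW HFHP replicate 1. Plasma cell genes were higher with no member past the threshold (median 2.28; limma camera adjusted p = 3.05e-05, adjusted p = 0.802 with an estimated correlation), as were MHC class II genes in median (0.32; limma camera adjusted p = 0.0388, adjusted p = 0.825 with an estimated correlation). With 1 library left out the plasma cell median ran from 0.33 (without NBW unnamed replicate 7) to 4.18 (without LBW unnamed replicate 7), and over the list alone 13 passed without LBW unnamed replicate 7. The MHC class II median ran from 0.21 (without LBW HFHP replicate 2) to 0.47 (without LBW unnamed replicate 3). With 1 surrogate variable both lists turned to the other direction, with adjusted p of 0.370 and 0.659. Mitochondrially encoded genes, a sign of RNA quality, had a median of -0.60 (limma camera adjusted p = 4.41e-04, adjusted p = 0.802 with an estimated correlation). Over the list alone 4 passed without NBW unnamed replicate 8. Skeletal muscle genes had a median of 2.37 (limma camera adjusted p = 0.00845, adjusted p = 0.802 with an estimated correlation). It ran from 0.38 to 2.89 with 1 library left out, and over the list alone 5 passed without NBW HFHP replicate 6. The cell cycle list was higher for the interaction with no member past the threshold (median 0.57; limma camera adjusted p = 2.15e-12, adjusted p = 0.802 with an estimated correlation). Over all genes edgeR called none, with 1366 at an unadjusted p under 0.05, and DESeq2 and limma voom called 1 each. The genes with the smallest p, not passing, were TAF2 (6.26 ± 1.37), HIVEP2 (0.86 ± 0.22) and CRTAM (1.18 ± 0.32) above 0. Below 0 they included TOLLIP (-0.68 ± 0.17) and ZADH2 (-0.68 ± 0.18).

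**Figure D1:**
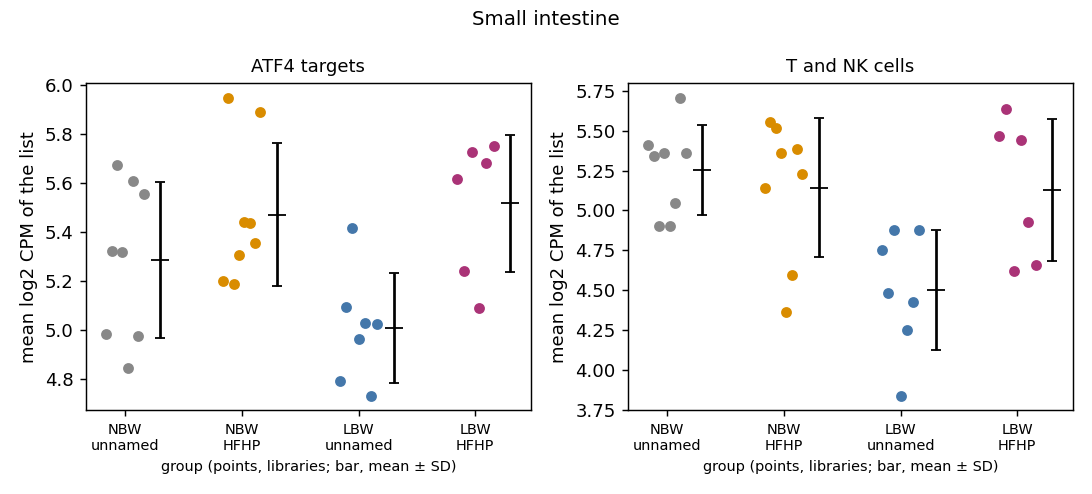
Mean log2 CPM (vertical axis) of the ATF4 target list and of the T and NK cell list in each small intestine library (points), by group (horizontal axis), with the group mean ± SD as a bar. LBW unnamed libraries had the lowest group means, 5.01 ± 0.22 for ATF4 targets and 4.50 ± 0.38 for T and NK cell genes.

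In the liver, cell cycle transcripts were lower and macrophage transcripts higher with HFHP. All 35 cell cycle genes had fold changes below 0 (median -0.80; limma camera adjusted p = 4.28e-31, adjusted p = 0.220 with an estimated correlation), and 21 passed over the list alone. The mitotic regulators CDC20 (-1.05 ± 0.29; chromosome 6, 167886266 to 167890587 of Sscrofa11.1), PLK1 (-0.89 ± 0.26), AURKA (-0.85 ± 0.26) and CCNB2 (-0.87 ± 0.27) each had an adjusted p over the list alone of 0.0237 by edgeR. CDC20 stood at 11.2 ± 6.59 CPM in NBW HFHP and 6.40 ± 3.63 CPM in LBW HFHP libraries, against 15.4 ± 3.88 CPM and 19.8 ± 5.42 CPM in the unnamed groups. The count was 12 without NBW unnamed replicate 3. All 17 macrophage genes had fold changes above 0 (median 0.22; limma camera adjusted p = 3.30e-11, adjusted p = 0.0561 with an estimated correlation), and 8 passed over the list alone, among them the 3 complement C1q chains C1QA (0.43 ± 0.10), C1QB (adjusted p over the list alone = 0.00926) and C1QC (0.35 ± 0.10), which lie side by side on chromosome 6, and TYROBP (0.31 ± 0.11). Leaving out any 1 of 9 of the 22 libraries moved this count by over 1.5 times, to 3 at the lowest without NBW unnamed replicate 1.

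Glucocorticoid target genes were higher in HFHP livers (median 0.34; limma camera adjusted p = 1.14e-04, adjusted p = 0.0924 with an estimated correlation), with the clock gene PER1 (0.47 ± 0.13) the 1 of 13 members past the threshold over the list alone. Without NBW unnamed replicate 2 no member passed, and without LBW HFHP replicate 1 there were 5, the count moving with 8 of the 22 libraries. The circadian clock list also had 1 member higher over the list alone (median 0.13), a count that moved with 13 of the 22 libraries. The gluconeogenesis list was higher with no member past the threshold (median 0.20; limma camera adjusted p = 0.00501, adjusted p = 0.536 with an estimated correlation), and its gatekeeping enzyme PCK1 had a fold change of 0.93 ± 0.33. That list's median ran from 0.11 (without LBW HFHP replicate 5) to 0.27 (without LBW HFHP replicate 1) with 1 library left out, and over the list alone 2 passed without LBW unnamed replicate 3. The gluconeogenesis mean went from 8.22 ± 0.14 log2 CPM unnamed to 8.24 ± 0.41 with HFHP in NBW, and from 8.15 ± 0.17 to 8.57 ± 0.27 in LBW libraries. Immediate early genes, a sign of RNA quality, had a median of 0.24 (limma camera adjusted p = 0.0410, adjusted p = 0.762 with an estimated correlation). It ran from 0.08 to 0.33 with 1 library left out, and over the list alone 1 passed without NBW unnamed replicate 5. T and NK cell genes had a median of 0.14 (limma camera adjusted p = 0.0208, adjusted p = 0.762 with an estimated correlation). It ran from 0.08 to 0.23 with 1 library left out, and over the list alone 1 passed without LBW unnamed replicate 6. IGFBP1, a binding protein of insulin-like growth factors, had 1.10 ± 0.39 without passing. The urea cycle list did not pass (median -0.05, limma camera unadjusted p = 0.286), nor did amino acid catabolism (median 0.06, limma camera unadjusted p = 0.294). Of 12545 genes none passed in edgeR, with 569 at an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. The smallest p-values not passing were those of FAM171A2 (0.41 ± 0.09), the cytokine subunit EBI3 (0.66 ± 0.14) and C1QA above 0. Those below 0 belonged to the mitotic gene TROAP (-1.26 ± 0.30), YWHAH (-0.38 ± 0.10) and KANK2 (-0.38 ± 0.10). Without NBW unnamed replicate 3 edgeR called 1 gene.

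In the liver, ATF4 targets tested lower in LBW piglets as a list (median -0.12; limma camera adjusted p = 0.00247, adjusted p = 0.858 with an estimated correlation), as did MHC class II genes (median -0.24; limma camera adjusted p = 7.81e-04, adjusted p = 0.858 with an estimated correlation). Amino acid catabolism genes tested higher (median 0.09; limma camera adjusted p = 0.00253, adjusted p = 0.858 with an estimated correlation). That median ran from 0.02 (without LBW HFHP replicate 5) to 0.15 (without NBW HFHP replicate 5) when 1 library was left out, and over the MHC class II list alone 4 passed without LBW unnamed replicate 6. The means were, for ATF4 targets, 4.89 ± 0.31 log2 CPM in LBW against 4.97 ± 0.25 in NBW unnamed libraries, and 4.72 ± 0.30 against 4.99 ± 0.38 with HFHP. For MHC class II they were 4.24 ± 0.48 log2 CPM in LBW against 4.32 ± 0.19 in NBW unnamed libraries, and 4.26 ± 0.35 against 4.64 ± 0.42 with HFHP. For amino acid catabolism they were 7.30 ± 0.20 log2 CPM in LBW against 7.30 ± 0.22 in NBW unnamed libraries, and 7.47 ± 0.26 against 7.21 ± 0.33 with HFHP. Genes of stellate cells and portal fibroblasts had a median of -0.15 (limma camera adjusted p = 0.0323, adjusted p = 0.858 with an estimated correlation). It ran from -0.26 to -0.11 with 1 library left out. With all libraries no list had a member past the threshold over the list alone. The smallest p-values in these lists belonged to the amino acid transporter SLC7A5 (-0.39 ± 0.20), the MHC class II chaperone CD74 (-0.27 ± 0.12) and AMT of glycine cleavage (0.54 ± 0.19). EdgeR called no gene, with 285 at an unadjusted p under 0.05, and DESeq2 and limma voom called 0. A share of 0.05 of the genes tested is 627, and random regroupings of the libraries had a median of 496. The genes with the smallest p, not passing, were EDRF1 (0.27 ± 0.07), DAPK1 (0.37 ± 0.11) and WIPI1 (0.36 ± 0.12) above 0. Below 0 they were the dendritic cell lectin CD207 (-6.48 ± 1.51), TMEM125 (-1.84 ± 0.45) and INKA2 (-0.72 ± 0.21). Without NBW unnamed replicate 3 edgeR called 1 gene.

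Interferon-stimulated genes departed from additive effects in the liver. The interferon list averaged 5.93 ± 0.69 log2 CPM in LBW unnamed (n = 6) and 5.85 ± 0.65 in NBW HFHP libraries (n = 6), and 5.19 ± 0.32 in LBW HFHP (n = 5) and 5.15 ± 0.35 in NBW unnamed libraries (n = 5). For the interaction 25 of 29 members were lower over the list alone (median -1.66; limma camera adjusted p = 1.06e-27, adjusted p = 0.331 with an estimated correlation), and the count stayed between 24 and 27 when single libraries were left out. The antiviral genes MX1 (-2.65 ± 0.61), ISG15 (-3.72 ± 0.93; chromosome 6, 63363201 to 63364211 of Sscrofa11.1), CMPK2 (-1.78 ± 0.44) and RSAD2 (-3.40 ± 0.91) had the smallest p, each with an adjusted p over the list alone of 0.00460 by edgeR. Mitochondrially encoded genes, a sign of RNA quality, were higher in the same 2 groups, with 10.10 ± 0.39 log2 CPM in NBW HFHP and 9.95 ± 0.55 in LBW unnamed, against 9.74 ± 0.37 in LBW HFHP and 9.70 ± 0.33 in NBW unnamed libraries (interaction median -0.52; limma camera adjusted p = 0.00193, adjusted p = 0.594 with an estimated correlation). Skeletal muscle transcripts moved with the same contrast: all 8 tested members were lower over the list alone (median -9.07; limma camera adjusted p = 8.12e-05, adjusted p = 0.594 with an estimated correlation), among them TNNT3 (-9.72 ± 2.34), MYLPF (-9.29 ± 2.28), ACTA1 (-9.57 ± 2.41) and TNNC2 (-8.90 ± 2.26). ACTA1 stood at 1556 CPM in LBW unnamed replicate 5, 155 CPM in NBW HFHP replicate 1 and 45.9 CPM in LBW unnamed replicate 2, and at or below 8.87 CPM in the other livers. Counts over the skeletal muscle list alone were 0 with limma voom, and its median ran from -9.36 (without NBW unnamed replicate 5) to -4.87 (without LBW unnamed replicate 5) with 1 library left out. Without these 3 libraries 22 interferon genes were lower over the list alone and no skeletal muscle gene was.

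In the same liver interaction HSPA5, the main chaperone of the endoplasmic reticulum, was higher over the heat shock list alone (1.15 ± 0.33) and DERL3, of protein export from that compartment, over the B and plasma cell list alone (3.32 ± 0.97). Neither list passed (limma camera adjusted p = 0.869 and 0.257). The HSPA5 call was lost on leaving out 1 of 2 libraries, NBW unnamed replicate 5 among them, and the DERL3 call on leaving out 1 of 12, NBW HFHP replicate 1 among them. The urea cycle list was higher without a member past the threshold (median 0.39; limma camera adjusted p = 0.00502, adjusted p = 0.594 with an estimated correlation), though 1 passed without NBW HFHP replicate 5, its smallest p-values belonging to OTC (0.45 ± 0.16) and ASS1 (0.82 ± 0.34). Genes of red blood cells and their precursors had a median of 0.85 (limma camera adjusted p = 0.0286, adjusted p = 0.594 with an estimated correlation). This median moved by over 1.5 times on leaving out single libraries, with 0.51 the lowest. Endothelial genes had a median of 0.16 (limma camera adjusted p = 0.0370, adjusted p = 0.594 with an estimated correlation). It ran from 0.08 to 0.33 with 1 library left out. EdgeR called no gene, with 688 at an unadjusted p under 0.05, whereas DESeq2 called 18 and limma voom 0. Besides MX1 and TNNT3, the smallest p-values not passing were those of CISD2 (0.96 ± 0.18), FNDC7 (9.16 ± 1.98), the cargo receptor LMAN1 (0.61 ± 0.13) and the interferon-induced EPSTI1 (-1.36 ± 0.30). Without NBW unnamed replicate 3 edgeR called 2 genes.

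**Figure D2:**
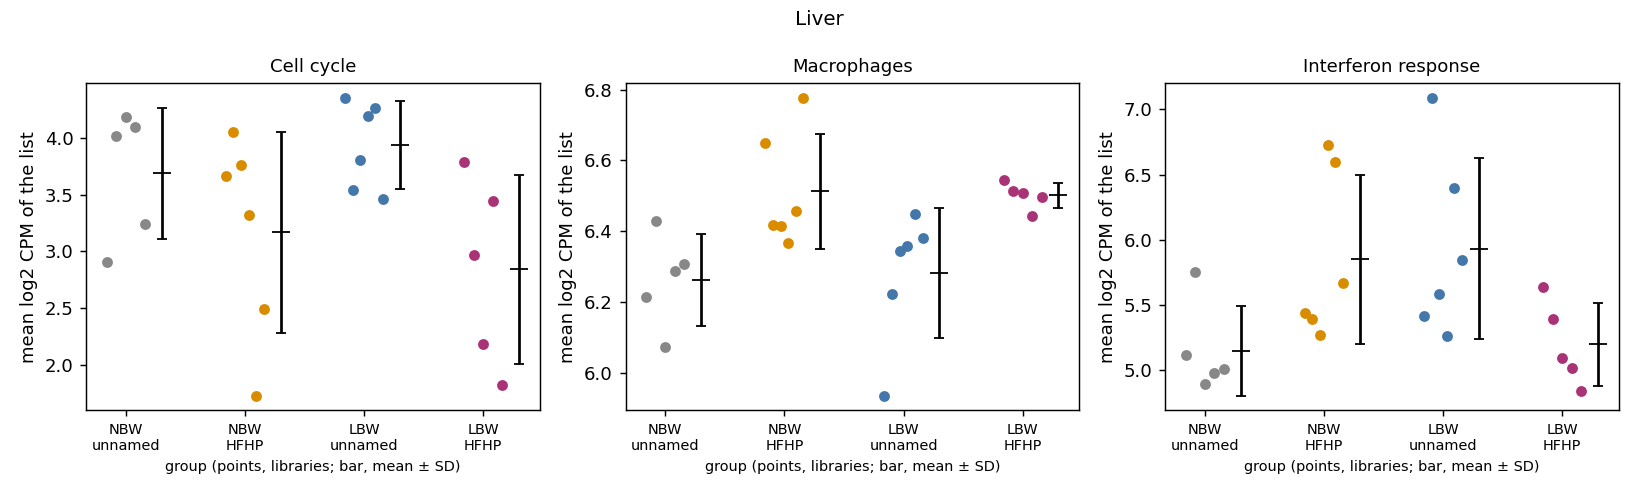
Mean log2 CPM (vertical axis) of the cell cycle, macrophage and interferon response lists in each liver library (points), by group (horizontal axis), with the group mean ± SD as a bar. Cell cycle means were 3.17 ± 0.89 and 2.84 ± 0.83 in the HFHP groups against 3.69 ± 0.58 and 3.94 ± 0.39 in the unnamed groups, with overlapping libraries.

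In muscle, chaperone transcripts were lower with HFHP. Of 12 heat shock genes 8 were lower over the list alone (median -0.30; limma camera adjusted p = 4.20e-08, adjusted p = 0.172 with an estimated correlation). They included the mitochondrial chaperonins HSPE1 (-0.53 ± 0.11, adjusted p over the list alone = 8.31e-04 by edgeR) and HSPD1 (-0.52 ± 0.12), neighbours on chromosome 15, the cytosolic chaperone HSP90AA1 (-0.28 ± 0.10) and its partner of the HSP70 system DNAJB1 (-0.24 ± 0.09). The list was fixed as a sign of RNA quality. Leaving out any 1 of 18 of the 24 libraries moved the count by over 1.5 times, down to 2 without NBW HFHP replicate 6, and the list median stayed between -0.33 and -0.26. All 45 oxidative phosphorylation genes had fold changes below 0 (median -0.23; limma camera adjusted p = 2.16e-12, adjusted p = 0.417 with an estimated correlation), without a member past the threshold; ATP5F1A had -0.28 ± 0.10 and NDUFS3 -0.34 ± 0.12. Slow fibre genes were lower (median -0.53; limma camera adjusted p = 5.11e-05, adjusted p = 0.417 with an estimated correlation) and fast fibre genes higher (median 0.34; limma camera adjusted p = 3.37e-06, adjusted p = 0.417 with an estimated correlation), again without a call among members; slow troponin TNNT1 had -0.68 ± 0.45 and the fast fibre actinin ACTN3 0.70 ± 0.27. The slow fibre mean went from 10.46 ± 0.68 log2 CPM unnamed to 9.79 ± 0.95 with HFHP in NBW, and from 10.02 ± 0.76 to 9.02 ± 2.02 in LBW libraries. TNNT1 stood at 26.4 CPM in LBW HFHP replicate 2, and the next lowest library, LBW unnamed replicate 1, had 592 CPM. The slow fibre median ran from -0.78 to -0.38 with 1 library left out. The fast fibre mean went from 11.73 ± 0.21 log2 CPM unnamed to 12.39 ± 0.69 with HFHP in NBW, and from 12.14 ± 0.38 to 12.28 ± 0.52 in LBW libraries. Over the fast fibre list alone 11 passed without LBW HFHP replicate 3.

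Averaged over both birth weight classes, the interferon list was higher with HFHP in muscle (median 0.42; limma camera adjusted p = 1.28e-09, adjusted p = 0.417 with an estimated correlation), as was the macrophage list (median 0.32; limma camera adjusted p = 8.26e-04, adjusted p = 0.330 with an estimated correlation). The interferon mean went from 3.04 ± 0.67 log2 CPM unnamed to 4.02 ± 0.54 with HFHP in NBW, and from 3.61 ± 0.67 to 3.66 ± 0.62 in LBW libraries. No member passed over either list alone; IFI6 had 1.02 ± 0.33 and CD68 0.45 ± 0.20. Of the interferon list 3 passed without NBW unnamed replicate 1. T and NK cell genes had a median of 0.43 (limma camera adjusted p = 0.00964, adjusted p = 0.417 with an estimated correlation). Over all 12355 genes edgeR called none, with 1120 at an unadjusted p under 0.05, against 61 by DESeq2 and 2 by limma voom. The smallest p-values not passing were those of the GABA receptor subunit GABBR1 (0.68 ± 0.13), the Fc receptor FCGR3A (0.78 ± 0.15) and the chemokine CXCL14 (0.77 ± 0.15) above 0. Those below 0 belonged to the splicing factor SRSF7 (-0.60 ± 0.11, adjusted p = 0.0838 over all genes by edgeR), HSPE1 and the HSP90 co-chaperone FKBP4 (-0.60 ± 0.13). Without LBW unnamed replicate 5 edgeR called 4 genes, and without NBW HFHP replicate 3, LBW HFHP replicate 2 or LBW unnamed replicate 1 it called 1.

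MHC class II transcripts were lower in muscle of LBW piglets. Of 9 genes tested 6 were lower over the list alone (median -0.46; limma camera adjusted p = 1.55e-08, adjusted p = 0.160 with an estimated correlation), including the class II transactivator CIITA (-0.46 ± 0.11, adjusted p over the list alone = 0.00330 by edgeR; chromosome 3, 32171706 to 32230775 of Sscrofa11.1), SLA-DMA (-0.76 ± 0.20), SLA-DMB (-0.42 ± 0.14) and SLA-DOA (-1.01 ± 0.36). The count stayed between 5 and 8 when single libraries were left out. Endothelial genes were lower as a list, all 15 with fold changes below 0 (limma camera adjusted p = 1.28e-06, adjusted p = 0.413 with an estimated correlation), as were adipocyte genes (median -0.93; limma camera adjusted p = 0.00464, adjusted p = 0.359 with an estimated correlation), neither with a member past the threshold. Their smallest p-values belonged to ECSCR (-0.55 ± 0.19) and ESAM (-0.50 ± 0.18) of endothelium and to the lipid droplet proteins PLIN4 (-0.35 ± 0.13) and PNPLA2 (-0.42 ± 0.18). Without NBW unnamed replicates 5 and 6, which had almost no cell cycle transcripts, 11 endothelial and 6 adipocyte genes passed over their lists alone. With limma voom 13 endothelial genes passed, with 1 surrogate variable 10 and with DESeq2 2. With 1 library left out, of the endothelial list at most 9 passed without LBW unnamed replicate 2, and of the adipocyte list 7 passed without NBW HFHP replicate 3. Developmental muscle genes were higher (median 0.13; limma camera adjusted p = 0.0144, adjusted p = 0.413 with an estimated correlation) without a call; the acetylcholine receptor subunit CHRNA1 had 0.37 ± 0.15 and cardiac actin ACTC1, expressed in immature muscle, 0.73 ± 0.31. That list's median ran from 0.11 (without NBW unnamed replicate 1) to 0.21 (without NBW unnamed replicate 5) with 1 library left out. The rise was not particular to LBW piglets. For the replacer, the median of the same list was 0.21 with HFHP, between 0.18 and 0.23 with 1 library left out.

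Single genes passed over other lists alone for birth weight in muscle, among them the T cell receptor chain CD247 (-0.51 ± 0.14) and the matrix protein THBS4 (-0.94 ± 0.26), both lower in LBW piglets. The CD247 call was lost on leaving out 1 of 3 libraries, NBW unnamed replicate 3 among them. The matrix count of 1 moved with 21 of the 24 libraries, between 0 without NBW HFHP replicate 2 and 4 without NBW HFHP replicate 3. The cell cycle list tested higher while its median was -0.02 and its mean 0.01 (limma camera adjusted p = 0.0144, adjusted p = 0.794 with an estimated correlation). With 1 library left out this median ran from -0.11 (without NBW unnamed replicate 6) to 0.10 (without NBW unnamed replicate 3), and the mean was 2.84 ± 0.75 log2 CPM in LBW against 2.19 ± 1.97 in NBW unnamed libraries, and 2.92 ± 0.39 against 2.80 ± 0.74 with HFHP. Immediate early genes, a sign of RNA quality, had a median of -0.26 (limma camera adjusted p = 0.0186, adjusted p = 0.760 with an estimated correlation). It ran from -0.45 to -0.05 with 1 library left out, and over the list alone 1 passed without NBW HFHP replicate 6. T and NK cell genes had a median of -0.29 (limma camera adjusted p = 0.0202, adjusted p = 0.760 with an estimated correlation). EdgeR called none of the 12355 genes, with 991 at an unadjusted p under 0.05, against 12 by DESeq2 and 2 by limma voom. The smallest p-values not passing were those of the coagulation inhibitor TFPI (0.82 ± 0.18), MTMR7 (0.79 ± 0.18) and CWC27 (0.43 ± 0.10) above 0. Below 0 they were those of the phosphodiesterase PDE2A (-0.60 ± 0.12), the cyclic AMP effector RAPGEF3 (-0.63 ± 0.12) and ACE, the angiotensin-converting enzyme (-0.82 ± 0.17). Without LBW unnamed replicate 2 edgeR called 2 genes.

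In muscle the interaction of matrix genes rested on few libraries. The tendon and cartilage genes COMP (-9.57 ± 2.25) and TNMD (-7.34 ± 1.99) were lower over the extracellular matrix list alone, and COMP stood at 220.1 CPM in NBW HFHP replicate 4 and 28.4 CPM in NBW HFHP replicate 2, with at most 4.47 CPM elsewhere. Neither passed without NBW HFHP replicate 4, and 4 members passed without NBW HFHP replicate 3. The interferon list was lower with no member past the threshold (median -0.87; limma camera adjusted p = 1.10e-15, adjusted p = 0.619 with an estimated correlation), RSAD2 having -2.34 ± 0.86 and OAS2 -1.40 ± 0.57. Hepatocyte genes had a median of 0.36 (limma camera adjusted p = 0.00649, adjusted p = 0.619 with an estimated correlation). It ran from 0.13 to 1.07 with 1 library left out. T and NK cell genes had a median of 0.62 (limma camera adjusted p = 0.0373, adjusted p = 0.632 with an estimated correlation). It ran from 0.34 to 0.98 with 1 library left out. EdgeR called no gene, with 225 at an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0. Besides COMP, the smallest p-values not passing were those of ODC1 (0.80 ± 0.25), ZNF862 (0.80 ± 0.26) and BEND3 (0.75 ± 0.25) above 0. Below 0 they were those of TIGD4 (-3.62 ± 0.78) and BASP1 (-2.73 ± 0.72).

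**Figure D3:**
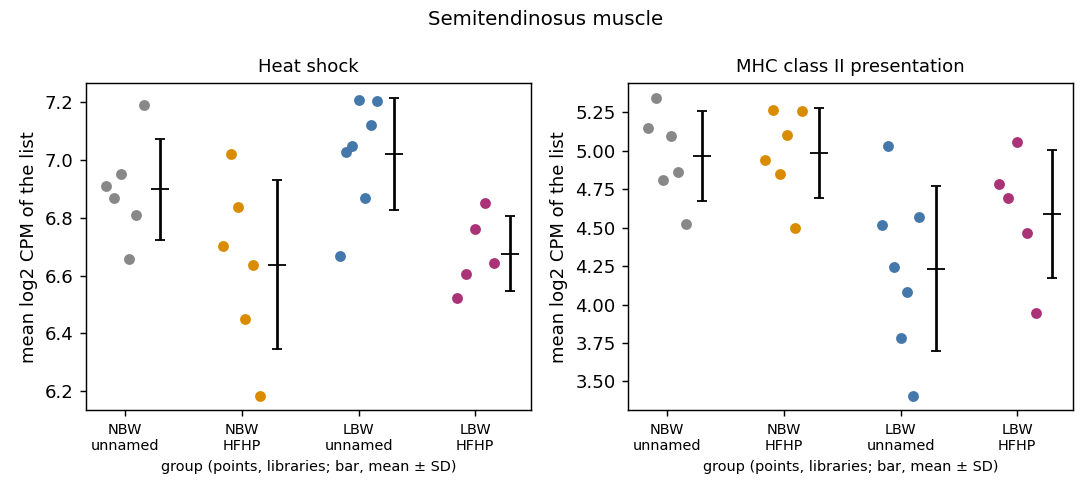
Mean log2 CPM (vertical axis) of the heat shock and MHC class II lists in each muscle library (points), by group (horizontal axis), with the group mean ± SD as a bar. Heat shock means were 6.64 ± 0.29 and 6.68 ± 0.13 with HFHP against 6.90 ± 0.18 and 7.02 ± 0.19 without, and MHC class II means 4.59 ± 0.42 and 4.23 ± 0.54 in LBW against 4.99 ± 0.29 and 4.97 ± 0.29 in NBW.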

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

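The patterns weighed here were found in the data and tested on the same data, and the tests of explanations were chosen after the patterns were seen. The tests of erythroid transcripts and of the place of LBW unnamed replicate 3 were written after related values had been seen. Regroupings are 100 splits of the libraries of a tissue into groups of the real sizes, the real one included. Over all 303 list results, 21 had a median as large in fewer than 5 of the 100 splits. Chance alone gives fewer than 15.2, the number at a share of 5 in 100, because the real split counts itself. Single list results have to be read against that bound. The lists below were picked from these after their results were seen, and the regroupings do not repeat the picking, so they do not exclude chance for a picked list.

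Amino acid transport, ATF4 targets and cell cycle differed between replacer labels in the small intestine together with markers of position. In the regroupings 1 of 100 splits had as many transporters in 1 direction over the list alone (7, highest other 4), 2 had as many ATF4 targets (10, highest other 11) and 8 as many cell cycle genes (13, highest other 34), so that chance could be excluded for the first 2 lists only had they not been picked. With GATA4 and FABP6 as covariates the effects on the mean log2 CPM were -0.36 ± 0.10, 0.34 ± 0.11 and 0.50 ± 0.16 (± SE), against -0.31 ± 0.11, 0.35 ± 0.11 and 0.41 ± 0.17 without, and with the proximal and distal marker lists as covariates -0.17 ± 0.10, 0.18 ± 0.11 and 0.22 ± 0.16, so position cannot be told apart from the replacer: the SE are too wide and the labels give no segment. LBW unnamed replicate 3, without which 1176 genes were called, lay at 0.916 between the other LBW unnamed libraries (0) and the LBW HFHP libraries (1, single libraries 0.420 to 1.30), but it was picked for its effect on the calls, so this place cannot decide whether it holds a sample of an HFHP piglet. LBW unnamed replicate 7 lay at 0.686, so a wide spread between piglets stays open too, as does the replacer itself as the difference that the design names.

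In the liver interaction, all 50 genes that most exceed liver in the muscle libraries stood at 2 times or more the median of the other livers in LBW unnamed replicate 5, and 48 and 46 of them in NBW HFHP replicate 1 and LBW unnamed replicate 2. Relative to the muscle libraries, their levels matched a share of muscle RNA of 1.91%, 0.142% and 0.0615%. The skeletal muscle signal is consistent with muscle tissue in these 3 samples. The interferon signal was as large in 4 of 100 regroupings (25 genes, highest other 28). Without the 3 libraries the interaction effect on its mean log2 CPM was -1.11 ± 0.41 (SE), against -1.44 ± 0.47 with them, which leaves open how much of it those samples carry.

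Lower cell cycle transcripts with HFHP in the liver were matched by 2 of 100 regroupings (21 genes, highest other 28), and higher macrophage transcripts by the real grouping only, 1 of 100 (8 genes, highest other 2). The totals argue against library size as the explanation, since their log2 differed by 0.00480 ± 0.0222 (SE) between replacer labels, against a cell cycle effect of -0.81 ± 0.30 on the mean log2 CPM. Dividing erythroid precursors, which newborn liver can hold, could not be excluded: the effect on the erythroid list was 0.08 ± 0.37, too uncertain to decide. The replacer stays open as the biological difference that the design names.

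The replacer effect on the cell cycle list differed between tissues: it was 0.41 in small intestine and -0.81 in liver on the log2 scale, a difference of 1.21 (permutation of the replacer labels within birth weight classes, 100000 resamples, two-sided p = 0.00107). The comparison was picked after both effects were seen, and the permutation does not repeat the picking. Labels were permuted apart in each tissue, although the tissues may share piglets. In small intestine alone, 8 of 100 regroupings had as many cell cycle genes over the list alone. Position could not be told apart from the replacer there.

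Of 88 group measures examined, 6 had 1 library far from the rest of its group, near the 5% that chance gives. In the small intestine, the skeletal muscle list averaged 4.21 log2 CPM in NBW unnamed replicate 4 (next 1.74) and the distal marker list 2.63 in LBW HFHP replicate 5 (next 5.98). In the liver, the interferon list averaged 5.75 in NBW unnamed replicate 2 (next 5.11) and the skeletal muscle list 4.19 in NBW HFHP replicate 1 (next 0.541). In muscle, mitochondrially encoded genes took 11.4% of the counts in NBW HFHP replicate 5 (next 6.14%) and the slow fibre list averaged 8.44 log2 CPM in LBW unnamed replicate 1 (next 9.80). The rule used the gap to the nearest library of the group, and it missed libraries described above. These were liver LBW unnamed replicate 5, with ACTA1 at 1556 CPM, and muscle LBW HFHP replicate 2, with TNNT1 at 26.4 CPM. The share near chance therefore does not show that the libraries were free of contamination.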

How the results depend on the processing

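The alternatives by covariates for GATA4 and FABP6 and those that leave out 2 or 3 libraries together were chosen after seeing the data, as were the results within LBW and within NBW piglets. EdgeR's 9 planned counts of 0 stayed 0 with RLE size factors, without a filter, with the strict filter, with robust estimation and without mitochondrially encoded genes. For the small intestine, DESeq2 called 16 genes for birth weight, 175 for the replacer and 1 for the interaction, and limma voom 86, 1504 and 1. In liver DESeq2 called 18 for the interaction. In muscle DESeq2 called 12 for birth weight, 61 for the replacer and 1 for the interaction, and limma voom 2, 2 and 0. A surrogate variable gave 4 genes for birth weight in small intestine, and 2 for birth weight and 19 for the replacer in muscle. For the replacer in small intestine, GATA4 and FABP6 as covariates gave 500 genes and leaving out the 2 libraries with almost no GATA4 gave 7; in muscle, leaving out NBW unnamed replicates 5 and 6 gave 2. For the replacer within LBW in small intestine, the count of 2 became 895 with DESeq2, 2556 with limma voom, 0 without a filter, 11 with the strict filter, 1 with a surrogate variable, 0 without mitochondrially encoded genes, 17 with the covariates and 585 without the 2 libraries. The count of 0 within NBW stayed 0 under every alternative run, leaving out single libraries included. The cause was not tested.

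Leaving out single libraries gave counts from 0 to 30 for birth weight, 0 to 1176 for the replacer, 0 to 0 for the interaction and 0 to 1784 for the replacer within LBW in small intestine. In liver they ran from 0 to 1, 0 to 1 and 0 to 2, and in muscle from 0 to 2, 0 to 4 and 0 to 0, for birth weight, replacer and interaction. The largest counts came without LBW unnamed replicate 3 in small intestine, NBW unnamed replicate 3 in liver, and LBW unnamed replicates 2 (birth weight) and 5 (replacer) in muscle.

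Same-numbered libraries deviated together in part. Correlations of their residuals averaged 0.062 in small intestine, 0.01 in liver and 0.135 in muscle, against -0.009, -0.002 and -0.024 for other numbers, and 11 of 40, 7 of 31 and 20 of 33 exceeded 0.1. They ran from -0.491 to 0.560, -0.279 to 0.242 and -0.317 to 0.422, and the best match had the same number for 9 of 29, 4 of 22 and 10 of 24 libraries. Not every pair exceeded 0.1, so the numbers were not taken to pair the libraries. This criterion cannot exclude a shared factor in any tissue, since such a factor need not raise every pair. No permutation was run within a tissue. The values of muscle leave a shared factor open most, and the main fits hold no term for it. With the replicate block edgeR called 1 gene for the interaction in small intestine, 7 for the replacer in muscle and 1272 for the replacer within LBW in small intestine, and 0 for the other results.

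Of 114 list calls, none held with an estimated correlation. Fry called 3 lists: macrophages for the replacer in liver (adjusted p = 0.0306), MHC class II for birth weight in muscle (adjusted p = 0.0324) and heat shock for the replacer in muscle (adjusted p = 0.0334). With 1 surrogate variable limma camera called 13, 9, 9, 8, 13, 15, 9, 16 and 10 lists, and with the replicate block 19, 22, 13, 9, 13, 13, 9, 14 and 9, against 15, 20, 12, 9, 12, 14, 11, 12 and 9 with neither, for birth weight, replacer and interaction in small intestine, liver and muscle in turn. With a surrogate variable the small intestine interaction of B and plasma cells (adjusted p = 0.370) and of MHC class II genes (adjusted p = 0.659) changed direction. No named gene reversed under any alternative run. The Y-linked covariate was not run, in tests of genes or of lists. With totals of 25.5 to 34.9 M counts (1e+06), depth limits genes near the filter.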

Other observations

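In the small intestine, plasma cell genes were higher with HFHP as a list (median 0.56; limma camera adjusted p = 9.24e-05, adjusted p = 0.505 with an estimated correlation), with the immunoglobulin joining chain JCHAIN (0.81 ± 0.25) and MZB1 (0.82 ± 0.27) past the threshold over the list alone. For this count, leaving out any 1 of 23 of the 29 libraries moved it by over 1.5 times, between 0 (without NBW HFHP replicate 1) and 15 (without NBW unnamed replicate 7). The mean went from 2.11 ± 1.68 log2 CPM unnamed to 2.15 ± 1.36 with HFHP in NBW, and from 2.01 ± 1.63 to 3.88 ± 2.26 in LBW libraries. The median ran from 0.22 (without NBW HFHP replicate 7) to 1.56 (without NBW unnamed replicate 7) with 1 library left out, and 68 of 100 regroupings of the libraries had a median as large, against 17 for the interaction. Macrophage genes were higher too (median 0.29; limma camera adjusted p = 1.51e-05, adjusted p = 0.497 with an estimated correlation), with the scavenger receptor CD163 at 0.89 ± 0.29 without passing; of this list 11 passed without LBW unnamed replicate 3. Adipocyte genes did not pass as a list, but PNPLA2 (-0.45 ± 0.12) and FABP4 (-1.03 ± 0.37) were lower over the list alone and LIPE higher (0.58 ± 0.23). The higher count of 1 was 0 on leaving out any 1 of 12 of the 29 libraries, and the lower count of 3 ran from 1 without LBW unnamed replicate 4 to 5 without LBW HFHP replicate 4.

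The results within LBW and within NBW piglets were chosen after the data were seen, and the other tests here before their values were. Regroupings of the libraries tested whether chance alone gives as many genes. For the calls of edgeR the real count was 0 in the 9 planned results, so that 100 of 100 splits reach it by definition and the splits test nothing there. Other splits called up to 243 genes for birth weight, 71 for the replacer and 37 for the interaction in small intestine. Only 5, 6 and 3 of these splits called any gene, for birth weight, replacer and interaction in turn. So few splits do not show a structure of the samples. Whether their large counts lie in single libraries, in an overlap with the real groups or elsewhere was not tested. Splits called up to 1, 1 and 1 in liver, and 1, 0 and 4 in muscle. At an unadjusted p under 0.05, the small intestine had 805 genes for birth weight (as many in 23 of 100 splits, highest other 3368), 2614 for the replacer (5, highest other 3105) and 1366 for the interaction (14, highest other 2799). Liver had 285 (90, highest other 1735), 569 (37, highest other 1454) and 688 (32, highest other 2056), and muscle 991 (22, highest other 3076), 1120 (9, highest other 2718) and 225 (85, highest other 3389). Chance could not be excluded at 0.05 for any of these 9 counts. For the replacer within LBW piglets in small intestine, 2 of 100 splits called as many genes as the real 2 (highest other 10), and 1 had as many at an unadjusted p under 0.05 (3177, highest other 2686). This contrast was picked for its size and the splits do not repeat the picking, so chance is not excluded for it: 1 other split reached 3368 genes in the birth weight contrast. Within NBW piglets 55 of 100 splits had as many genes at an unadjusted p under 0.05 (475, highest other 2958), and the real count of 0 calls (highest other 2) tests nothing. For birth weight in liver 0 of 34 lists had a median as large in fewer than 5 of 100 splits, where chance gives fewer than 1.70. ATF4 targets, MHC class II and amino acid catabolism had one in 29, 27 and 39 splits.

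A hypothesis was that libraries with the same group and number in 2 tissues came from the same piglet. If so, their deviations from the group means were to correlate more than those of other numbers in all 3 pairs of tissues. The mean correlation across genes was -0.033 between small intestine and liver (one-sided permutation p = 0.966, 10000 permutations of numbers within groups), 0.011 between small intestine and muscle (permutation p = 0.256) and 0.050 between liver and muscle (permutation p = 0.0183). The 3 pairs went different ways, and the data do not decide whether numbers mark piglets.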
